A study of Mus musculus with 12 samples.

How the data were processed

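RNA-seq was carried out on polyadenylated RNA of mouse N2A neuroblastoma cells, harvested 48 h after transfection of siRNA pools or of a non-targeting pool. Per the labels, 1000 ng of RNA went into each library, fragmentation was shortened and the inserts had a mean length of 540 nt. The 12 libraries formed 6 groups of 2: control set A, Rnps1 knockdown, control set B, and knockdown of Srrm3 with Srrm4, of Srsf11 and of Rbfox2. Set A (4 libraries) and set B (8 libraries) are in separate deposited tables, each with its own controls, so groups were compared within a set only. The processing notes name bcl2fastq and edgeR without versions and the genome build mm9, and the splicing tables name vast-tools. The aligner, the counting tool and the version of vast-tools are not given in the sources used here. Positions are in mm9 as deposited.

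Per the file headers, the deposited expression tables hold read counts per gene and library, and whole numbers in these columns fit that unit. The authors also gave a log2 fold change per knockdown against its control and an FDR, a p-value adjusted for the number of genes, and the processing notes name edgeR for this. The deposited splicing tables hold, per event and library, corrected numbers of inclusion and exclusion reads made by the authors with vast-tools. Further tables by the authors give 1 percentage of inclusion (PSI, percent spliced in) per group and a call of differential events, and the rule behind that call is not stated. The 24 columns of normalised expression and of PSI per library were not used. PSI was recomputed from the inclusion and exclusion reads, in place of the deposited PSI that had been planned. Libraries carry the letters of the table columns, which cannot be matched to replicate numbers. The letters of control set A and Rnps1 knockdown are a and b in both kinds of table, and those of set B differ (control set B is c and d in the expression table and c and b in the splicing table).

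The expression tables list 22667 genes, of which 1114 have no count. Genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM scaling, the quasi-likelihood test and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Set A gave 12361 tested genes with a biological coefficient of variation of 0.0898, and set B 12737 tested genes with 0.0419. The 3 knockdowns of set B were fitted together, so that the groups share 1 estimate of the spread. The counts of the 2 libraries of a group differed beyond counting noise, with a chi-square per degree of freedom between 3.25 and 22.2, so neither library of a group is a copy of the other.

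The splicing tables list 283013 events: 1193 microexons of at most 27 nt, 52948 longer exons, 158677 introns, and 39661 alternative acceptor and 30524 alternative donor sites, with no position for 10 events in set A and 7 in set B. Events needed at least 10 reads in every library, and were left out where PSI was under 1 or above 99 in every library. Inclusion and exclusion reads of all classes were fitted in 1 edgeR quasi-likelihood model per set with an intercept per library and a group effect on inclusion. An event was called at an adjusted p under 0.05 and a PSI difference of at least 10 points. Alternative sites were counted as events with at least 1 called site, without a direction. Microexons were compared with longer exons by Fisher's exact test, 2-sided, and shares of called exons that fell carry Clopper-Pearson 95% intervals. Overlaps of calls in the same direction were set against the product of both counts over the number tested, with Fisher's exact test, adjusted over the 18 overlap tests. The 3 knockdowns of set B share 2 control libraries. Unchanged groups were simulated against these controls, 20 times for the covariance and 5 times for the test. No microexon was called to fall in the latter, so that the test says nothing about overlaps. For microexons of mid-range inclusion, Srrm3/Srrm4 and Srsf11 knockdown were later each set against another control library. Knockdowns of set B were also contrasted directly.

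Gene lists were written before the data were examined, from general knowledge. They are SR proteins (20 genes), hnRNP proteins (24), neuronal splicing regulators (30), the exon junction complex (20), factors (17) and targets (28) of nonsense-mediated decay, the integrated stress response (30), p53 targets (30), interferon response (35), S phase (30), G2 and M phases (30), replication-dependent histones (24), neuronal differentiation (48), sympathoadrenal genes (20), axon guidance (34), cholesterol synthesis (25), glycolysis and hypoxia (28), the unfolded protein response (20), mitochondrially encoded genes (13), ribosomal proteins (40), markers of fibroblasts (22), glia (20) and immune cells (18), long neuronal genes (20) and known microexon genes (98). Of 687 genes 661 were found. Lists share genes: Srsf2, Srsf3, Srsf7, Tra2a and Tra2b are SR proteins and decay targets, Upf2, Upf3b, Smg1 and Smg5 decay factors and targets, Atf3, Atf4 and Ddit3 stress genes and decay targets, and 10 genes are long neuronal and microexon genes. Camera (limma 3.58.1) was run with a preset correlation of 0.01 and with an estimated one, each adjusted over the 24 lists tested per knockdown, and fry beside it. Knockdown targets stayed in their lists, and the list tests were not rerun without them. Named genes follow a rule fixed before the data were examined: the targets, per knockdown the 8 rising and 8 falling genes with the largest log2 fold change, a mean of at least 5 CPM and no overlap between libraries, and up to 4 members per list with the smallest adjusted p. For splicing the rule takes the 8 microexons, 4 longer exons, 3 introns and 3 alternative sites with the largest PSI difference and no overlap. Some items that meet the rule are not reported here. Genes outside the rule are said to be chosen after their values were seen.

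Counts of changed genes and named genes were recomputed with DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter, a filter of 5 CPM in 2 libraries, a minimum 2-fold change, the 4 libraries of the 2 groups alone, and without each library in turn, as far as each applies. Gene lists were retested with the estimated correlation only. For splicing the alternatives were 20 or 5 reads, a PSI difference of 15 points, limma on log2 odds (offset 0.5), a rule of 15 points with a gap of 5 between libraries in place of a test, microexons of at most 15 or 51 nt, and a control PSI of 20 to 80. In groups left with 1 library, that library was assumed to vary like the other groups. Sequencing batches are not given in the labels.

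The tests were tried on simulated data with 200 changed features. In 5 simulations of genes, 64.2% of those changed 1.5-fold and 84.2% of those changed 2-fold were recovered for set A, and unchanged genes made up 10.7% of the calls, above the 5% aimed at. For set B the shares were 80.2%, 88.6% and 6.95%. Genes were first simulated once and then 5 times to steady these shares. For splicing events 0% and 10% of those changed by 20 and 30 points were recovered for set A and 6% and 44% for set B. A simulation with 2000 changed events, added because the recovery was low, gave 4.1% and 37.1% for set A and 20.9% and 58.1% for set B, with at most 1 unchanged event called. An event that was not called is therefore not shown to be unchanged. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and the R package data.table in version 1.17.8.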

Results

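N2A cells, a line from a mouse neuroblastoma (a tumour of immature nerve cells), were transfected with pools of small interfering RNA (siRNA), and polyadenylated RNA was sequenced 48 h later. The 12 libraries formed 6 groups of 2. Control set A and the knockdown of Rnps1 were in 1 pair of tables. Control set B and the knockdowns of Srrm3 with Srrm4, of Srsf11 and of Rbfox2 were in another, so these 3 knockdowns shared 2 control libraries. The series concerns the factors that govern neuronal microexons, exons of at most 27 nt that are included mainly in nerve cells. Srrm3 and Srrm4 are neural splicing regulators of such exons, Rnps1 is a peripheral protein of the exon junction complex, Srsf11 belongs to the serine/arginine-rich (SR) splicing factors, and Rbfox2 binds the motif UGCAUG near alternative exons. The gene counts summed to 39935710 and 30173140 in control set A, 36269737 and 26406230 with Rnps1 knockdown, and 36345542 and 33118711 in control set B. They summed to 38769597 and 34899850 with Srrm3/Srrm4 knockdown, 49105592 and 36252235 with Srsf11 knockdown, and 39905914 and 34675174 with Rbfox2 knockdown. The reads assigned to splicing events ranged from 33086831 to 69162862 per library. Values below are means ± SD of 2 libraries (SD, n = 2 per group) in CPM (counts scaled to library size) or in percent inclusion (PSI), log2 changes carry their standard error, and p-values are adjusted values from edgeR unless another test is named. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. Binomial intervals cover counting error only.

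Each siRNA pool lowered its target. Rnps1 mRNA (ENSMUSG00000034681) fell from 288 ± 2.69 to 9.60 ± 0.668 CPM, which left 3.34% of the control level (log2 change -4.90 ± 0.09, adjusted p = 5.89e-07). Srsf11 mRNA (ENSMUSG00000055436) fell from 225 ± 7.97 to 20.8 ± 2.37 CPM, which left 9.25% (adjusted p = 1.85e-16), and Rbfox2 mRNA (ENSMUSG00000033565) from 213 ± 7.36 to 31.1 ± 1.03 CPM, which left 14.6% (adjusted p = 4.69e-16). The double knockdown was the weakest: Srrm3 (ENSMUSG00000039860) fell from 35.8 ± 0.816 to 9.76 ± 0.800 CPM (27.3% left, adjusted p = 1.83e-11) and Srrm4 (ENSMUSG00000063919) from 69.5 ± 2.25 to 29.1 ± 1.90 CPM (41.9% left, adjusted p = 1.58e-10). The targets also moved with other pools. Rbfox2 fell to 66.6% of control with Rnps1 knockdown (log2 change -0.59 ± 0.07, adjusted p = 0.000823) and to 79.8% with Srsf11 knockdown (adjusted p = 1.60e-05). Rnps1 fell to 76.4% with Srsf11 knockdown (adjusted p = 1.09e-06) and to 80.3% with Rbfox2 knockdown (adjusted p = 2.01e-05). Srrm4 rose to 135% with Rbfox2 knockdown (adjusted p = 8.73e-06), and Srrm3 to 118% with Srsf11 knockdown (adjusted p = 0.00364). Srsf11 stood at 88.0% with Rbfox2 knockdown (adjusted p = 0.0121), a call that ended without Rbfox2 library a (adjusted p = 0.0538) or b (0.0715). With Rnps1 knockdown Srrm3 stood at 93.1% (adjusted p = 0.433) and Srrm4 at 107% (adjusted p = 0.578), which passed as a rise without control library b (adjusted p = 0.0386).

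**Figure D1:**
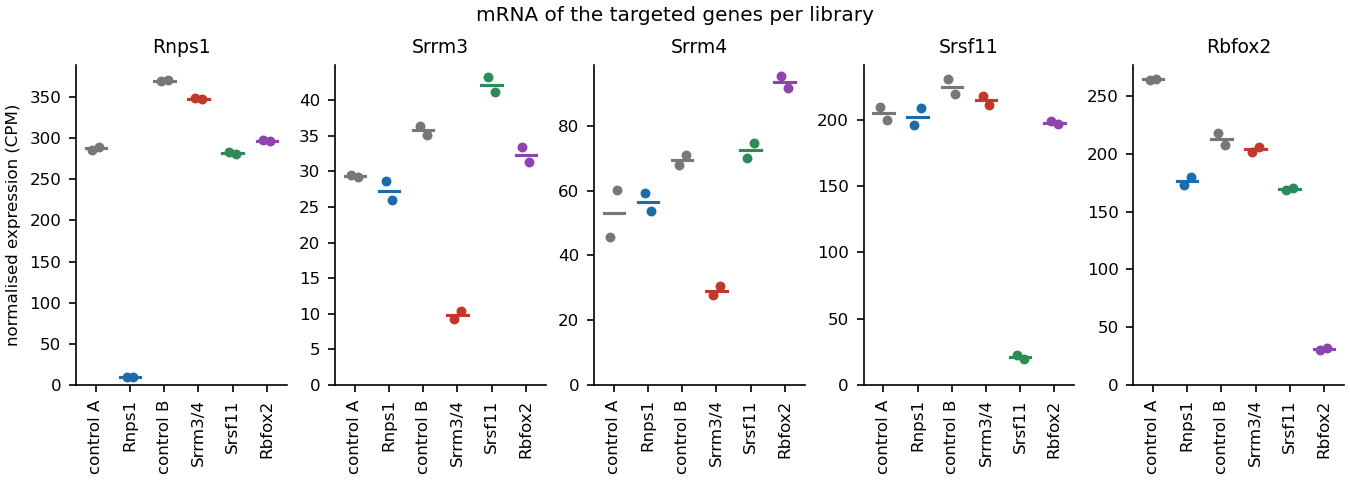
Level of the 5 targeted genes in CPM (vertical axis, linear from 0) per library in the 6 groups; points are libraries and bars are means of 2 libraries. Each target was lowest in the libraries of its own knockdown, down to 9.60 CPM for Rnps1 with Rnps1 knockdown.

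Knockdown of Srrm3 and Srrm4 lowered the inclusion of microexons. Of 587 microexons tested, 126 in 115 genes fell and the other 461 did not pass, with a median change among the 126 of -40.2 points. The 6-nt exon of Git2, which encodes a GTPase-activating protein for Arf proteins (mm9 chromosome 5, 115203157 to 115203162), fell from 82.6 ± 1.69% to 6.87 ± 3.69% PSI (50 to 74 reads per library, adjusted p = 2.09e-13). The 24-nt exon of Clasp2, a microtubule plus-end protein (chromosome 9, 113787868 to 113787891), fell from 80.5 ± 0.00580% to 3.85 ± 0.0509% (53 to 75 reads, adjusted p = 5.15e-14). The 15-nt exon of Vav2, a signalling protein (chromosome 2, 27155950 to 27155964), fell from 86.3 ± 2.61% to 10.1 ± 0.140% (78 to 214 reads, adjusted p = 7.19e-27). The 9-nt exon of Myo5a, a vesicle motor (chromosome 9, 75035329 to 75035337), fell from 97.6 ± 0.113% to 25.6 ± 0.653% (256 to 300 reads, adjusted p = 1.17e-56). The remaining microexons chosen by rule, in Bbs9, Vav2, Cdon and Hook2, fell by 69.8 to 76.8 points. Among 25899 longer exons 23 rose and 77 fell. A 33-nt exon of Acbd5 (chromosome 2, 22936188 to 22936220) fell from 70.5 ± 0.985% to 6.29 ± 0.466%, an 81-nt exon of Reep6 by 62.5 points (adjusted p = 0.000225 with edgeR and 0.0874 with limma), a 30-nt exon of Meaf6 by 59.8 points and a 45-nt exon of Asph by 59.2 points. Among 45001 introns 14 rose and 8 fell, and 13 of 15811 alternative splice site events changed. An acceptor site of Cask (chromosome X, 13114887 to 13114952), a synaptic scaffold, fell from 70.6 ± 4.52% to 4.41 ± 0.547% and 1 of Fsd1l from 89.1 ± 3.85% to 20.8 ± 5.98%. Limma on log2 odds called 42 microexons, 16 longer exons and 4 alternative sites, ended the calls for the exons of Cdon (adjusted p = 0.0592) and Hook2 (0.0934), and called 0 introns (2058 at an unadjusted p under 0.05, against 510 with edgeR). The 22 introns became 14 without control library c, control library b or knockdown library c, and the 13 alternative sites 8 without control library c and 7 without knockdown library a.

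With the same knockdown, genes of the neuronal differentiation list lost expression. Of 44 measured genes of neuronal differentiation 26 fell, 2 rose and 16 did not pass (27 fell and 2 rose adjusted over the list alone), with a camera adjusted p of 2.28e-25 and an adjusted p = 0.0395 with an estimated correlation. Snap25, a fusion protein of synaptic vesicles, fell from 170 ± 4.08 to 77.8 ± 2.31 CPM (log2 change -1.12 ± 0.05), the neurofilament gene Nefh from 126 ± 3.28 to 58.9 ± 3.50 CPM (-1.10 ± 0.06), and the secretogranin Scg2 from 326 ± 5.53 to 171 ± 5.37 CPM (-0.93 ± 0.05). Where no other count is given, the counts adjusted over the list alone were equal. Napb, which encodes a partner of vesicle fusion, fell most of the genes chosen by rule, from 92.1 ± 3.84 to 14.1 ± 2.12 CPM (-2.71 ± 0.08). Grin1, the obligate subunit of NMDA receptors, fell from 17.3 ± 1.01 to 4.77 ± 0.647 CPM (-1.86 ± 0.10). Mpp3, Pgbd5, Reep6, Cpne1, Trim67 and Sncg fell by 1.40 to 1.98 on the log2 scale. Among 24 neuronal splicing regulators 10 fell and 2 rose (13 and 4 adjusted over the list alone, camera adjusted p = 1.16e-06, adjusted p = 0.172 with an estimated correlation), which include the targets Srrm3 and Srrm4, Celf4 (-1.39 ± 0.07) and Elavl4 (-0.64 ± 0.07). The list was not retested without both targets, whose fall was the aim of the knockdown. Celf4 and Elavl4 are also in the neuronal differentiation list.

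The genes that rose with Srrm3/Srrm4 knockdown included Myl9, Cdon and Col4a1. Myl9, a myosin light chain, rose from 4.28 ± 0.161 to 27.6 ± 0.253 CPM (2.69 ± 0.09). Cdon, a cell-surface receptor that binds hedgehog, rose from 15.2 ± 0.574 to 66.7 ± 1.22 CPM (2.13 ± 0.07), and Col4a1, a collagen chain of basement membranes, from 286 ± 20.4 to 1113 ± 23.3 CPM (1.96 ± 0.06). Itga8, Fam198b, Fam114a1, Cntnap2 and Kif1c rose by 1.57 to 1.75. Cdon and Col4a1 each held a fallen microexon: the 14-nt exon of Cdon (chromosome 9, 35283315 to 35283328) went from 78.2 ± 7.26% to 6.25 ± 3.52% (16 to 131 reads, adjusted p = 1.16e-07 with edgeR and 0.0592 with limma), and the 17-nt exon of Col4a1 (chromosome 8, 11204536 to 11204552), named after its values were seen, from 24.9 ± 3.87% to 0.875 ± 0.601% (adjusted p = 9.25e-52). Fibroblast markers were higher as well: 5 of 11 measured rose and 6 did not pass (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.310 with an estimated correlation). Of these, Fn1 (fibronectin) went from 512 ± 57.7 to 744 ± 6.32 CPM (0.54 ± 0.06) and Fbn1 (fibrillin) from 35.6 ± 0.697 to 51.2 ± 2.63 CPM (0.52 ± 0.06).

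Metabolic groups moved by small amounts in these cells. Of 22 measured genes of cholesterol synthesis 20 fell and 2 did not pass (camera adjusted p = 8.04e-13, adjusted p = 0.0506 with an estimated correlation). Fdft1, the squalene synthase, fell from 215 ± 1.15 to 152 ± 2.21 CPM (-0.50 ± 0.05), and Lss, the lanosterol synthase, from 342 ± 1.97 to 256 ± 11.9 CPM (-0.42 ± 0.05). Of 26 genes of glycolysis and hypoxia 10 rose and 16 did not pass (camera adjusted p = 6.15e-05, adjusted p = 0.557 with an estimated correlation), among them the glycolytic kinase Pgk1 from 650 ± 28.9 to 976 ± 160 CPM (0.59 ± 0.09) and P4ha2, a collagen prolyl hydroxylase, from 106 ± 15.4 to 176 ± 4.95 CPM (0.72 ± 0.07). Of 20 genes of the unfolded protein response 8 rose (9 adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.446 with an estimated correlation), with the chaperones Hspa5 (0.31 ± 0.05) and Hsp90b1 (0.32 ± 0.05). Of 30 S-phase genes 12 fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 0.0287, adjusted p = 0.318 with an estimated correlation), with the replication helicase genes Mcm2 (-0.28 ± 0.06) and Mcm6 (-0.23 ± 0.05). In all 3474 of 12737 genes changed, 1579 up and 1895 down (1586 up and 1579 down with a filter of 5 CPM), of which 278 changed at least 2-fold, 185 up and 93 down. Without knockdown library b 2116 genes changed.

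Knockdown of Rnps1 lowered the inclusion of many exons and raised the retention of introns. Of 547 microexons 109 fell and 4 rose, so that 96.5% of the called ones fell (Clopper-Pearson 95% interval 91.2 to 99%), with a median change of -27.6 points. The 24-nt exon of Sh3glb1, a membrane-bending endophilin (chromosome 3, 144362818 to 144362841), fell from 70.7 ± 1.52% to 10.7 ± 3.17% (305 to 493 reads, adjusted p = 1.94e-27). The 4-nt exon of Asap2, an Arf GTPase-activating protein (chromosome 12, 21220228 to 21220231), fell from 95.6 ± 3.19% to 35.9 ± 10.6% (103 to 158 reads, adjusted p = 1.48e-15). The 27-nt exon of Dock4, a Rac exchange factor (chromosome 12, 41521184 to 41521210), fell from 83.4 ± 1.53% to 28.3 ± 3.75% (133 to 372 reads, adjusted p = 2.98e-16). The 12-nt exon of Mta1, a subunit of a chromatin remodeller (chromosome 12, 114373012 to 114373023), fell from 82.3 ± 2.47% to 31.9 ± 1.15% (181 to 367 reads, adjusted p = 4.65e-15). The exons of Git2 and Snap91 fell by 59.6 and 55 points with edgeR, and limma gave adjusted p of 0.0715 and 0.0557. Among 23576 longer exons 1432 fell and 168 rose. A 75-nt exon of Ppfia2, a synaptic scaffold (chromosome 10, 106204530 to 106204604), fell from 95.3 ± 1.33% to 4.18 ± 2.40% (63 to 105 reads, adjusted p = 6.89e-29), 1 of Raph1 by 78.4 points and 1 of Pecr by 76.8 points. A 183-nt exon of Thrap3 rose by 80.3 points (14 to 37 reads, adjusted p = 1.30e-08 with edgeR and 0.0536 with limma). Among 40834 introns 604 rose and 107 fell, and an intron of the GABA receptor gene Gabbr1 (chromosome 17, 37185552 to 37186721) rose from 16.3 ± 0.583% to 100% in both libraries (12 to 80.5 reads, adjusted p = 6.77e-12). Of 14214 alternative site events 227 changed, among them donor sites of Atp6v0a2 (100% to 4.49 ± 3.09%) and Glt8d1 (6.63 ± 0.00655% to 93.1 ± 3.53%). Limma called 20 microexons, 396 longer exons, 118 introns and 77 alternative sites. Without knockdown library a the edgeR counts were 75, 954, 344 and 121.

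The messages that rose with Rnps1 knockdown included those of its partners. Pnn, which encodes a partner of Rnps1 in the exon junction complex, rose from 140 ± 27.7 to 413 ± 10.8 CPM (log2 change 1.56 ± 0.13), and Acin1, another partner, from 187 ± 22.2 to 423 ± 19.0 CPM (1.18 ± 0.10). In the exon junction complex list 9 of 18 rose and 2 fell, Rnps1 among them (9 and 3 adjusted over the list alone, camera adjusted p = 0.623). Of 15 factors of nonsense-mediated decay, which removes messages with early stop codons, 10 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.0428, adjusted p = 0.921 with an estimated correlation). Ncbp2, the small cap-binding protein, rose from 38.4 ± 2.83 to 73.4 ± 4.29 CPM (0.94 ± 0.09), Upf3a by 0.57 ± 0.08 and Upf1 by 0.39 ± 0.08. Of 19 known targets of that decay 9 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0972), with Atf3 up 1.28 ± 0.17 and Tra2a down (-0.73 ± 0.10). Some targets are also in other lists, Tra2a and Tra2b among the SR proteins, of which 9 rose and 3 fell of 19 (9 and 4 adjusted over the list alone, camera adjusted p = 0.455). The RNA-binding protein gene Rbmx rose from 16.6 ± 3.40 to 104 ± 7.44 CPM (2.65 ± 0.14). Fam186b, Avil, Ptprt, Lrrc2, Kcnmb2 and Yjefn3 rose by 2.26 to 3.68. Lix1 (2.72 ± 0.68) passed with edgeR (adjusted p = 0.0135) and not with DESeq2 (0.0795).

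Histone, neuronal and hypoxia-related messages fell with Rnps1 knockdown. The 4 measured replication-dependent histone genes fell (camera adjusted p = 4.49e-06, adjusted p = 0.921 with an estimated correlation), with Hist1h1c from 16.6 ± 2.70 to 0.991 ± 0.131 CPM (-4.05 ± 0.22). Messages of such genes mostly lack a poly(A) tail, and these libraries held polyadenylated RNA. The histone variant gene H2afx fell from 38.8 ± 4.50 to 2.47 ± 0.0492 CPM (-3.97 ± 0.15) and Cnn2, a calponin, from 124 ± 15.1 to 10.2 ± 2.13 CPM (-3.62 ± 0.16). Of 43 genes of neuronal differentiation 22 fell and 4 rose (camera adjusted p = 0.000135, adjusted p = 0.921 with an estimated correlation), with synapsin Syn1 from 69.1 ± 2.43 to 15 ± 0.210 CPM (-2.20 ± 0.09) and the adhesion molecule L1cam from 341 ± 24.9 to 85.0 ± 5.73 CPM (-2.00 ± 0.09). Of 26 genes of glycolysis and hypoxia 18 fell and 1 rose (camera adjusted p = 0.000135, adjusted p = 0.921 with an estimated correlation), with the neuronal enolase Eno2 (-2.17 ± 0.22) and Adm, a vasodilator peptide induced by hypoxia (-3.84 ± 0.39). These genes also varied between libraries of 1 group: Bnip3 stood at 316 and 215 CPM in control set A and at 43.8 and 110 CPM with Rnps1 knockdown. Of 22 cholesterol genes 7 fell and 15 did not pass (camera adjusted p = 0.0428, adjusted p = 0.969 with an estimated correlation), with Tm7sf2 at -2.37 ± 0.21. Of 26 interferon-response genes 10 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0428, adjusted p = 0.921 with an estimated correlation), at low levels such as 1.13 ± 0.0383 to 4.04 ± 0.472 CPM for Isg15. Olfml2a, Fam196b and Ank fell by 2.93 to 3.47. In all 5979 of 12361 genes changed, 2855 up and 3124 down, of which 1448 changed at least 2-fold.

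Knockdown of Srsf11 lowered the inclusion of a smaller set of microexons. Of 587 tested 63 fell and 3 rose, with a median change of -20.7 points. The 9-nt exon of Nbea, a scaffold of synaptic membrane traffic (chromosome 3, 55797970 to 55797978), fell from 87.4 ± 0.670% to 13.3 ± 2.99% (82 to 126 reads, adjusted p = 8.66e-20). The 27-nt exon of Ncor1, a corepressor of nuclear receptors (chromosome 11, 62216938 to 62216964), fell from 57.6 ± 1.95% to 17.1 ± 0.736% (444 to 627 reads, adjusted p = 6.69e-22 with edgeR and 0.0575 with limma). The exon of Git2 fell from 82.6 ± 1.69% to 36.7 ± 0.322% (74 to 147 reads, adjusted p = 1.34e-05 with edgeR and 0.130 with limma). The exons of Mtss1l, Snx14 and Daam1 fell by 38.3 to 40.5 points with edgeR, with limma adjusted p of 0.170, 0.123 and 0.134. That of Tmco4 fell by 43.1 points, which did not pass with limma (0.320) or without control library c (0.170). The exon of Clasp2 stood at 80.5 ± 0.00580% and 43.2 ± 0.209% (adjusted p = 0.00521), a call that ended without control library c (0.0789) or b (0.0543), without knockdown library a (0.0912) or b (0.0699), and with limma (0.137). Among 25899 longer exons 591 fell and 90 rose. A 30-nt exon of Unc13a, a priming factor of synaptic vesicles (chromosome 8, 74160437 to 74160466), fell from 84.8 ± 2.88% to 22.4 ± 7.78% (204 to 305 reads, adjusted p = 8.04e-27) and a 35-nt exon of Slc9a8 from 91.8 ± 2.02% to 19.4 ± 14.1% (14 to 48 reads, adjusted p = 1.33e-05). Of 45001 introns 84 rose and 26 fell, and of 15811 alternative site events 70 changed. Limma called 5 microexons, 33 longer exons, 4 introns and 2 alternative sites. The 66 microexons became 40 without control library c, 38 without knockdown library a and 43 without b, the 681 longer exons 425 without a and 448 without b, the 110 introns 59 without control c, 50 without a, 60 without control b and 72 without b, and the 70 alternative sites 46, 33, 38 and 42 in the same order.

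Messages of splicing factors and of sterol synthesis fell together with Srsf11 knockdown. Of 22 hnRNP genes 20 fell and 2 did not pass (21 fell adjusted over the list alone, camera adjusted p = 2.72e-07, adjusted p = 0.147 with an estimated correlation), with Hnrnpa0 from 138 ± 3.40 to 70.8 ± 3.46 CPM (-0.96 ± 0.05) and Hnrnph1 from 1101 ± 14.9 to 619 ± 18.8 CPM (-0.83 ± 0.05). Of 19 SR protein genes 15 fell and 1 rose (camera adjusted p = 3.05e-06, adjusted p = 0.0632 with an estimated correlation), Srsf11 among them, with Srsf1 from 599 ± 22 to 400 ± 3.22 CPM (-0.58 ± 0.05). Of 18 genes of the exon junction complex list 13 fell and 1 rose (camera adjusted p = 0.0109, adjusted p = 0.262 with an estimated correlation), with the export helicase Ddx39b at -0.69 ± 0.05. Ptbp2, the neuronal paralogue of the polypyrimidine tract-binding protein, fell from 175 ± 10.1 to 31.5 ± 1.5 CPM (-2.47 ± 0.06). Of 22 cholesterol genes 22 fell (camera adjusted p = 6.49e-20, adjusted p = 0.0260 with an estimated correlation), with Lss from 342 ± 1.97 to 133 ± 1.96 CPM (-1.36 ± 0.05) and Cyp51, the lanosterol demethylase, from 316 ± 8.93 to 127 ± 0.406 CPM (-1.32 ± 0.05). Of 40 ribosomal protein genes 30 fell and 10 did not pass (camera adjusted p = 0.00387, adjusted p = 0.341 with an estimated correlation), with Rpl4 at -0.44 ± 0.05.

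Growth and stress groups also moved with Srsf11 knockdown. Of 30 S-phase genes 17 fell and 4 rose (camera adjusted p = 0.00387, adjusted p = 0.147 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, from 194 ± 13.5 to 50.9 ± 3.07 CPM (-1.94 ± 0.06). Of 9 replication-dependent histone genes 7 fell and 2 did not pass (8 fell adjusted over the list alone, camera adjusted p = 3.17e-05, adjusted p = 0.147 with an estimated correlation), with Hist1h1c from 17.4 ± 1.13 to 1.69 ± 0.0930 CPM (-3.37 ± 0.13). Of 28 genes of the integrated stress response 19 fell and 2 rose (20 and 2 adjusted over the list alone, camera adjusted p = 0.00211, adjusted p = 0.350 with an estimated correlation), with the mTOR inhibitor gene Ddit4 at -1.52 ± 0.07 and Nupr1 at 1.44 ± 0.07. Of 26 genes of glycolysis and hypoxia 18 fell and 1 rose (camera adjusted p = 0.00242, adjusted p = 0.455 with an estimated correlation), with Bnip3, a mitophagy receptor, from 75 ± 1.97 to 11.8 ± 5.95 CPM (-2.63 ± 0.19). Of 27 interferon-response genes 21 rose and 2 fell (camera adjusted p = 8.52e-06, adjusted p = 0.147 with an estimated correlation), from low levels: Isg15 went from 1.09 ± 0.0390 to 7.61 ± 0.165 CPM (2.80 ± 0.17) and Rsad2 from 0.300 ± 0.0184 to 3.80 ± 0.191 CPM (3.66 ± 0.27). Fibroblast markers were higher beside these groups, with 8 of 11 up and 3 that did not pass (camera adjusted p = 0.0163, adjusted p = 0.257 with an estimated correlation), such as Vim (0.42 ± 0.05) and S100a4 (1.37 ± 0.09). Clu (clusterin), a secreted chaperone, rose from 0.991 ± 0.103 to 24.4 ± 0.810 CPM (4.62 ± 0.13) and Myl9 from 4.28 ± 0.161 to 45.1 ± 1.96 CPM (3.40 ± 0.08). Padi4, Sorbs3, Galnt5, Lrrc36, Glt8d2 and Col28a1 rose by 3.42 to 4.29. Csda, a Y-box protein gene, fell from 357 ± 2.26 to 51.3 ± 2.63 CPM (-2.80 ± 0.05), and Tgfbi, Hist1h2bc, Brp44l and Stra6 fell by 2.29 to 2.72. In all 8449 of 12737 genes changed, 4177 up and 4272 down (4228 and 4219 with DESeq2 size factors, 3552 and 3429 with a filter of 5 CPM, 4005 and 3877 with the 4 libraries of both groups alone), and of the 1626 that changed at least 2-fold 1311 rose.

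Knockdown of Rbfox2 changed exons of many lengths, and some microexons rose. Of 587 microexons 40 fell and 13 rose, so that 75.5% of the called ones fell (Clopper-Pearson 95% interval 61.7 to 86.2%). The 12-nt exon of Tead1, a transcription factor of the Hippo pathway (chromosome 7, 119999567 to 119999578), fell from 96.1 ± 0.691% to 9.05 ± 5.17% (149 to 213 reads, adjusted p = 5.32e-55). The 24-nt exon of Uggt1, a sensor of glycoprotein folding (chromosome 1, 36233621 to 36233644), fell from 99.1 ± 0.560% to 20.9 ± 1.08% (203 to 310 reads, adjusted p = 2.40e-65). The exons of Celsr3, Diap1, Fmnl1, Dtnb and Csnk1g3 fell by 57.5 to 80.7 points. Among 25899 longer exons 531 fell and 64 rose. A 273-nt exon of Fn1 (chromosome 1, 71660337 to 71660609) fell from 95.8 ± 0.128% to 3.38 ± 2.71% (308 to 431 reads, adjusted p = 8.83e-126). A 57-nt exon of Clstn1, a calsyntenin of neuronal vesicle traffic (chromosome 4, 149015767 to 149015823), fell from 88.0 ± 0.127% to 2.59 ± 0.877% (871 to 1091 reads, adjusted p = 3.97e-216). Exons of Fmnl3 and Tbc1d23 fell by 88.7 and 85.7 points. Of 45001 introns 89 rose and 18 fell, with an intron of Adam23 at 7.69 ± 8.54% and 81.3 ± 6.21% (adjusted p = 4.53e-06 with edgeR and 0.0528 with limma), and of 15811 alternative site events 43 changed. Limma called 18 microexons, 98 longer exons, 8 introns and 3 alternative sites. Without control library c 391 longer exons, 47 introns and 22 alternative sites were called, without knockdown library d 48 introns and 23 alternative sites, and without control library b 61 introns and 23 alternative sites.

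Proliferation, sterol and glycolytic messages fell with Rbfox2 knockdown. Of 30 genes of the G2 and M phases 26 fell and 4 did not pass (28 fell adjusted over the list alone, camera adjusted p = 8.43e-09, adjusted p = 0.180 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, fell from 492 ± 24.6 to 243 ± 32.9 CPM (-1.01 ± 0.08), Ccnb2 (cyclin B2) from 101 ± 1.25 to 60.5 ± 2.48 CPM (-0.74 ± 0.05) and Aurkb, a mitotic kinase, by 0.83 ± 0.07. Of 30 S-phase genes 16 fell and 14 did not pass (camera adjusted p = 0.00998, adjusted p = 0.249 with an estimated correlation), with Ccne1 (cyclin E1) at -0.68 ± 0.05. Of 22 cholesterol genes 21 fell and 1 did not pass (camera adjusted p = 3.09e-08, adjusted p = 0.133 with an estimated correlation), with Sc5d at -0.61 ± 0.05. More cholesterol and S-phase genes fell than rose with each of the 3 knockdowns of set B, which share 2 control libraries. A shift in these controls would move all 3 alike, and this was not tested. With Rnps1 knockdown, which has other controls, 7 of 22 cholesterol genes fell, and 13 of 30 S-phase genes rose and 4 fell. Of 26 genes of glycolysis and hypoxia 22 fell and 4 did not pass (camera adjusted p = 7.70e-08, adjusted p = 0.393 with an estimated correlation), with Tpi1, a glycolytic isomerase, from 612 ± 53.7 to 204 ± 38.3 CPM (-1.59 ± 0.10). Some genes of this list also differed between the control sets, in CPM scaled within each set. Bnip3 stood at 316 and 215 CPM in control set A and at 76.4 and 73.6 CPM in control set B. Adm stood at 23.9 and 21.3 against 2.78 and 2.50 CPM, and Ndrg1 and Pgk1 were also higher in control set A. The changes of this list in the 4 knockdowns were not set apart from such variation. The lactate exporter Slc16a3 fell from 253 ± 24.9 to 55.8 ± 17.6 CPM (-2.19 ± 0.16). Stx1a, a fusion protein of the presynaptic membrane, fell from 58.2 ± 8.46 to 15.3 ± 0.361 CPM (-1.93 ± 0.09), and Sspn, a partner of the dystrophin complex, from 14.2 ± 0.467 to 1.01 ± 0.174 CPM (-3.80 ± 0.14). Ndrg1, Bnip3, Tmem50b, Pnpla3 and Gnb3 fell by 1.93 to 2.70.

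Some long neuronal and axon guidance genes rose with Rbfox2 knockdown. Of 16 long neuronal genes 10 rose and 1 fell (camera adjusted p = 0.000320, adjusted p = 0.249 with an estimated correlation), with Nfasc (neurofascin), an adhesion molecule of the axon initial segment, from 5.76 ± 1.11 to 35.5 ± 0.243 CPM (2.62 ± 0.10) and its anchor Ank3 from 103 ± 5.93 to 177 ± 3.10 CPM (0.78 ± 0.05). Of 22 axon guidance genes 11 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.00667, adjusted p = 0.302 with an estimated correlation), with the semaphorin receptor Nrp1 from 195 ± 10.6 to 354 ± 8.40 CPM (0.86 ± 0.05). Of 11 fibroblast markers 8 rose and 1 fell (camera adjusted p = 3.04e-05, adjusted p = 0.133 with an estimated correlation), with Fbn1 from 35.6 ± 0.697 to 123 ± 6.33 CPM (1.79 ± 0.06). More of these markers rose than fell with the other knockdowns of set B too, where a shift in the shared controls could add. With Rnps1 knockdown 3 of 10 rose and 5 fell. Of 27 interferon-response genes 16 rose and 2 fell (camera adjusted p = 0.00520, adjusted p = 0.180 with an estimated correlation), with the RNA sensor gene Ddx58 from 1.29 ± 0.323 to 5.47 ± 0.337 CPM (2.07 ± 0.18). Megf10, an engulfment receptor, rose from 2.80 ± 0.383 to 33.2 ± 1.69 CPM (3.57 ± 0.11), and the growth factor gene Tgfb3 from 10.6 ± 0.683 to 47.4 ± 0.439 CPM (2.16 ± 0.07). Galnt5, Itga2, Prokr1, Prickle2 and Ptprr rose by 2.09 to 3.06. In all 7092 of 12737 genes changed, 3460 up and 3632 down (3073 up and 3021 down with a filter of 5 CPM), of which 900 changed at least 2-fold, 741 up and 159 down.

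**Figure D2:**
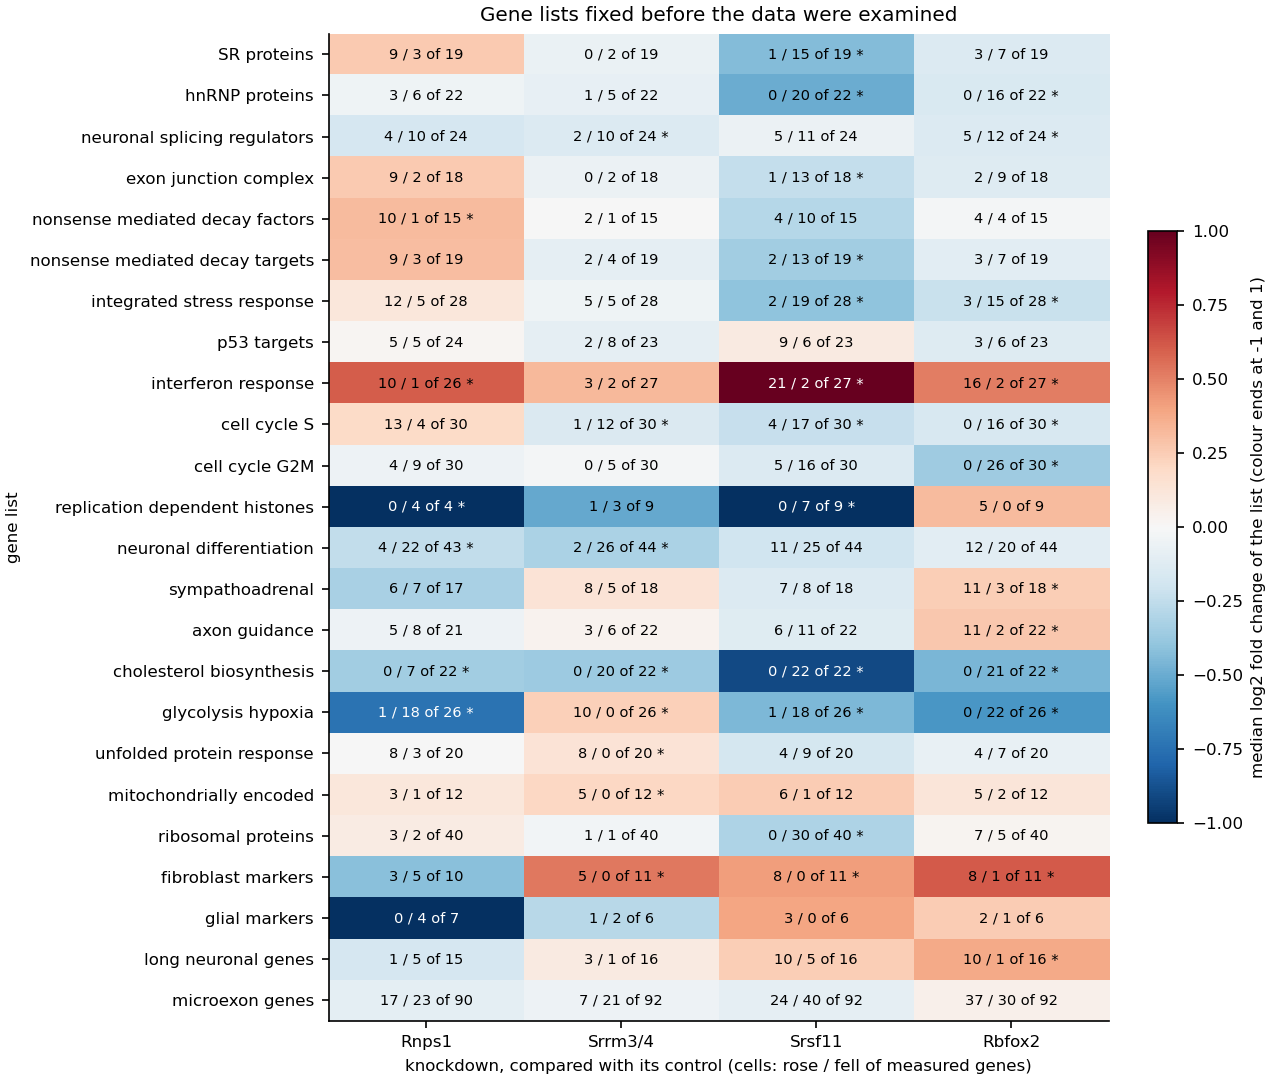
Median log2 fold change (colour, limited to -1 and 1) of each gene list in each knockdown against its control; cells give genes that rose and fell of those measured, and an asterisk marks a camera adjusted p under 0.05 at a preset correlation. Cholesterol synthesis has 22 of 22 genes down with Srsf11 knockdown, and with an estimated correlation 2 of the marked cells keep their call, this one and neuronal differentiation with Srrm3/Srrm4 knockdown.

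Microexons were called more often than longer exons in each knockdown, and the gap was widest for Srrm3/Srrm4. With that knockdown 21.5% of microexons and 0.386% of longer exons were called (odds ratio 70.4, 95% interval 52.8 to 93.9, Fisher exact test, 2-sided, p = 5.40e-150). With Rnps1 knockdown the shares were 20.7% and 6.79% (odds ratio 3.58, 2.86 to 4.44, exact p = 2.12e-25), with Srsf11 knockdown 11.2% and 2.63% (4.69, 3.53 to 6.14, exact p = 8.87e-22) and with Rbfox2 knockdown 9.03% and 2.30% (4.22, 3.08 to 5.68, exact p = 3.18e-16). By length (3 to 15, 16 to 27, 28 to 51, 52 to 100, 101 to 200 and over 200 nt) 25.5, 18.6, 1.78, 0.317, 0.0889 and 0.177% of exons fell with Srrm3/Srrm4 knockdown. With Rnps1 knockdown the shares were 20.3, 19.7, 7.04, 5.28, 6.06 and 7.96%, so that the longest exons fell more often than those of 52 to 200 nt. They were 14, 8.43, 5.16, 2.89, 1.58 and 1.53% with Srsf11 and 5.35, 7.85, 4.09, 2.16, 1.79 and 1.49% with Rbfox2 knockdown. Of 60 genes in the list of known microexon genes, 86 microexons were tested in set A and 88 in set B. Of these, 41 fell with Srrm3/Srrm4 knockdown, 34 with Rnps1, 19 with Srsf11 and 10 with Rbfox2 (49, 42, 24 and 10 adjusted over the list alone), and 3 rose with Rbfox2 and 1 with Srsf11. Exons are not independent replicates, and the tests describe the exons of these libraries. With a limit of 51 nt the odds ratio was 25.4 for Srrm3/Srrm4, 1.67 for Rnps1, 3.01 for Srsf11 and 2.76 for Rbfox2. With exons of control PSI 20 to 80 it was 27.8 for Srrm3/Srrm4 and 3.07 for Srsf11. With limma calls it was 124 for Srrm3/Srrm4, 2.22 for Rnps1 and 8.33 for Rbfox2. In both settings the knockdowns without a value here also kept an odds ratio above 1 with a Fisher exact p under 0.05.

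**Figure D3:**
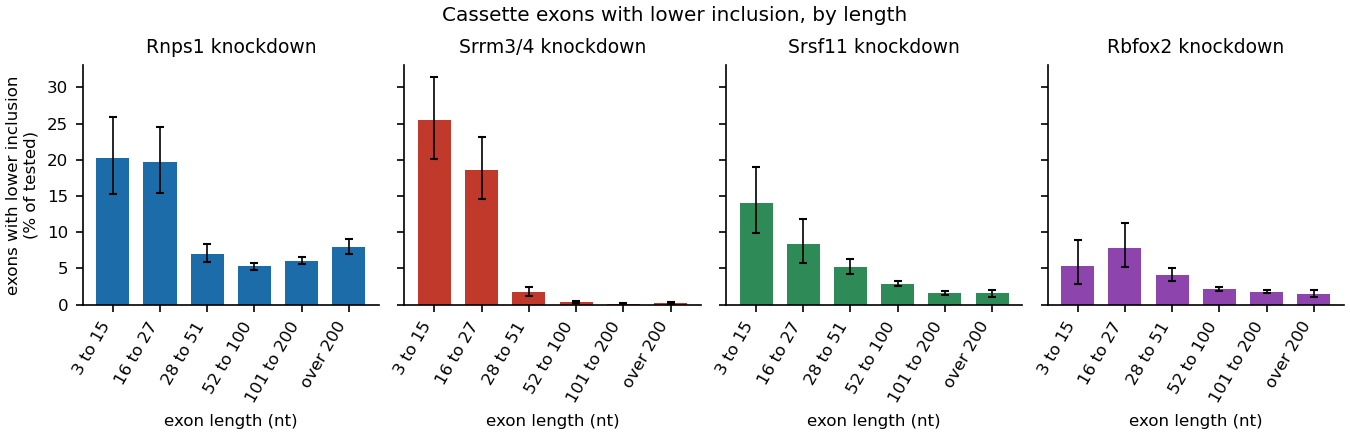
Share of tested exons that fell (vertical axis, percent, from 0) by exon length in nt (horizontal axis) in the 4 knockdowns; error bars are Clopper-Pearson 95% intervals. With Srrm3/Srrm4 knockdown the share drops from 25.5% at 3 to 15 nt to 1.78% at 28 to 51 nt.

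Many microexons that depended on Srrm3 and Srrm4 also fell when Rnps1 or Srsf11 was lowered. Of 486 microexons tested in both tables, 108 fell with Rnps1 knockdown, 124 with Srrm3/Srrm4 knockdown and 72 with both, where 27.6 would be shared by chance (odds ratio 12.4, Fisher exact test, 2-sided, p = 6.90e-26, adjusted p = 2.48e-25 over 18 overlap tests). These knockdowns have separate controls. The chance counts here treat all tested microexons alike, whatever their inclusion or reads. At a control PSI of 20 to 80, 32 of 57 microexons that fell with Srrm3/Srrm4 knockdown also fell with Rnps1 knockdown. Of those not called with Srrm3/Srrm4 knockdown 17 of 63 fell (odds ratio 3.43, Fisher exact p = 0.00154). Of 587 microexons 42 fell with both Srrm3/Srrm4 and Srsf11 knockdown, where 13.5 would be shared by chance. Rnps1 and Srsf11 knockdown shared 32 (14 by chance, adjusted p = 1.44e-07) and Rnps1 and Rbfox2 knockdown 28 (8.89 by chance, adjusted p = 2.89e-11). Rbfox2 knockdown shared 15 fallen microexons with Srrm3/Srrm4 (8.59 by chance) and 15 with Srsf11 knockdown (4.29 by chance). No p is given for these overlaps of the 3 pairs with shared controls, since the exact test takes both sets as independent and part of these overlaps can come from the controls. In the set tested in all 4 knockdowns 24 microexons fell with Rnps1, Srrm3/Srrm4 and Srsf11 knockdown and 7 with all 4. The 24 include those of Git2, Clasp2, Sh3glb1, Mta1 and Mef2d, a transcription factor, chosen after their values were seen. With Srsf11 knockdown limma called 5 microexons, and the calls of Git2 and Clasp2 ended there. That of Clasp2 also ended without single libraries. The exon of Sh3glb1 fell by 60, 53.8 and 21.2 points and that of Mta1 by 50.4, 59.4 and 23.1 points with Rnps1, Srrm3/Srrm4 and Srsf11 knockdown. Across microexons, which are not independent replicates, the PSI differences with Rnps1 and Srrm3/Srrm4 knockdown had a Pearson correlation of 0.661 and a Spearman correlation of 0.562. For knockdowns with shared controls a correlation arises without any effect: unchanged groups simulated against the same controls gave a mean of 0.536, and the observed value for Srrm3/Srrm4 and Srsf11 was 0.497. Their covariance of 92.4 lay above the 20 simulated ones, of which the highest was 8.92. For Rbfox2 with Srrm3/Srrm4 and with Srsf11 the observed correlations were 0.0761 and 0.0995 against simulated means of 0.493 and 0.534, and the covariances 17.9 and 12.3 against simulated maxima of 7.96 and 8.11. The overlap of Rnps1 and Srsf11 became 17 without control library c, 15 without Srsf11 library a and 19 without Srsf11 library b, and that of Srrm3/Srrm4 and Srsf11 became 25, 24 and 25. The overlap of Srsf11 and Rbfox2 became 9 with a PSI difference of at least 15 points.

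**Figure D4:**
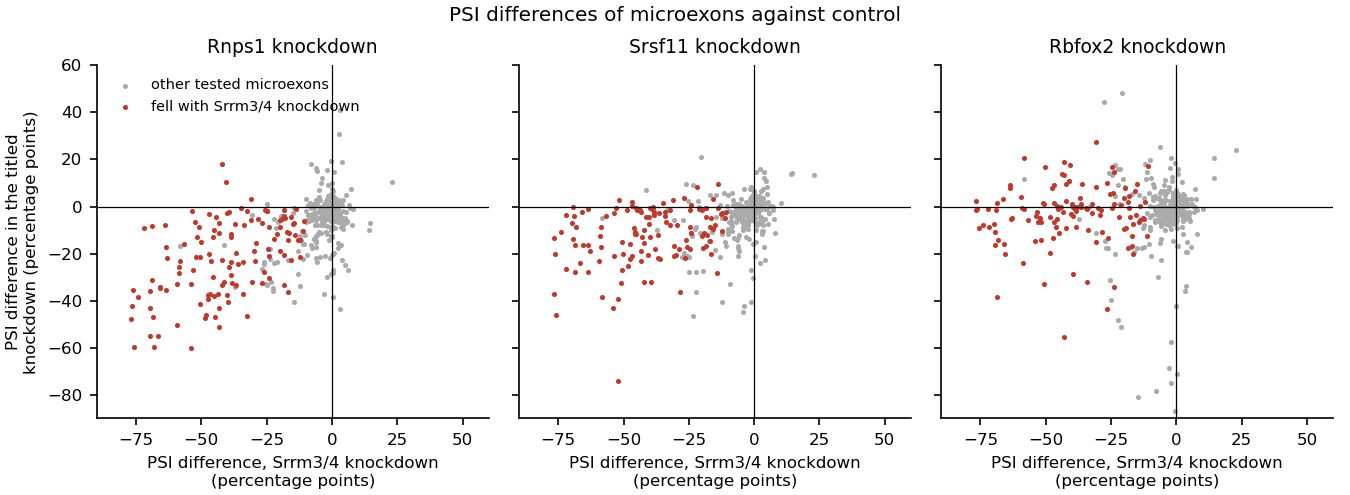
PSI difference of each microexon with Srrm3/Srrm4 knockdown (horizontal axis, percentage points) against that with Rnps1, Srsf11 or Rbfox2 knockdown (vertical axis, percentage points); red points fell with Srrm3/Srrm4 knockdown. The red points lie mostly below 0 for Rnps1, where 72 of 124 fell, and lie on both sides of 0 for Rbfox2, where 15 of 126 fell and 8 rose.

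Direct contrasts within set B showed where the knockdowns differed. Between Srrm3/Srrm4 and Srsf11 knockdown 118 microexons differed, 101 of them lower with Srrm3/Srrm4, and between Srrm3/Srrm4 and Rbfox2 knockdown 156 differed, 135 of them lower with Srrm3/Srrm4. Between Srsf11 and Rbfox2 knockdown 93 differed, 66 of them lower with Srsf11 (55 in all without Srsf11 library a). Among longer exons the direction turned: 631 of 759 were higher with Srrm3/Srrm4 than with Srsf11 knockdown, and 588 of 727 higher than with Rbfox2 knockdown. Among genes 8428, 7395 and 8607 differed between Srrm3/Srrm4 and Srsf11, Srrm3/Srrm4 and Rbfox2, and Srsf11 and Rbfox2. Rnps1 knockdown was in other tables and was not contrasted directly with the others.

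**Figure D5:**
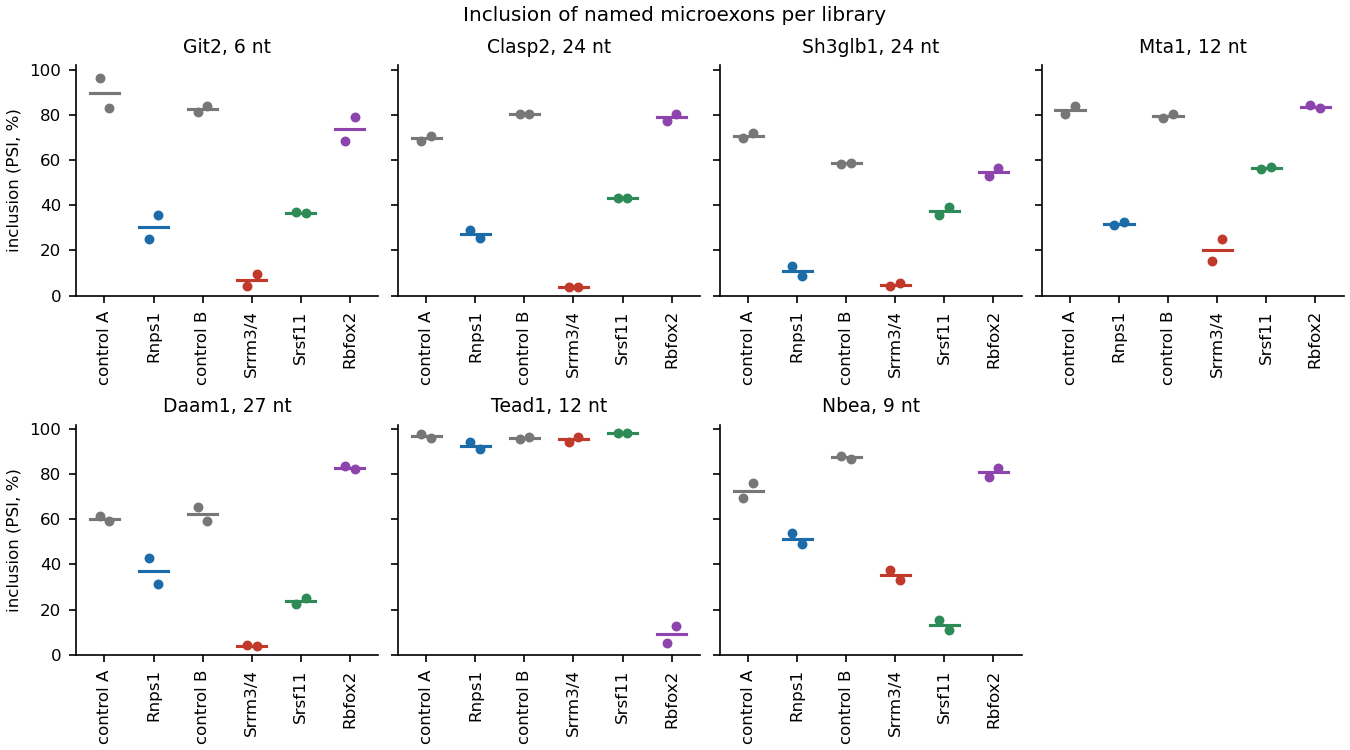
Inclusion in percent (vertical axis, from 0) of 7 microexons in each library of the 6 groups; points are libraries and lines are means of 2 libraries. The Git2 exon stands at 82.6% in control set B, 6.87% with Srrm3/Srrm4 knockdown and 36.7% with Srsf11 knockdown, and the Tead1 exon is low in the Rbfox2 libraries at 9.05%.

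The deposited tables also hold the authors' calls. At the authors' false discovery rate under 0.05, 6732 genes were called with Rnps1 knockdown, 3552 with Srrm3/Srrm4, 8675 with Srsf11 and 7233 with Rbfox2, and 5871, 3398, 8282 and 6894 of them were also called here. Of the authors' differential microexons, 110 with Rnps1 knockdown, 134 with Srrm3/Srrm4, 83 with Srsf11 and 58 with Rbfox2, the test used here called 94, 115, 60 and 44, each in the authors' direction. Of their differential introns, 938, 56, 284 and 304 in the same order, the test used here called 539, 8, 51 and 65.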

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

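The direct contrasts between knockdowns were planned; the restriction to microexons, after 42 opposite calls in 33 exons had been counted, each per exon and pair of knockdowns (14 in 9 microexons and 28 in 24 longer exons), and the tests without single libraries were chosen after the results were seen. Microexons were singled out here because 2 knockdowns sharing controls moved them in opposite directions and a direct contrast between both knockdowns passed. A shift in the shared controls moves both differences the same way and so works against opposite calls. No explanation was tested for these exons.

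Inclusion was lower with Srrm3/Srrm4 knockdown and higher with Rbfox2 knockdown for 8 microexons. The firmest were those of Ptk2, focal adhesion kinase (mm9 chromosome 15, 73112648 to 73112665, 18 nt), and Hook3, a microtubule linker protein (chromosome 8, 27156378 to 27156383, 6 nt). The Ptk2 exon stood at 66.1 ± 2.33% in control set B, 22.9 ± 2.18% with Srrm3/Srrm4 knockdown and 85.1 ± 0.905% with Rbfox2 knockdown (SD, n = 2), a direct difference of -62.2 points (edgeR adjusted p = 8.19e-57). The Hook3 exon stood at 79.5 ± 3.96%, 29.3 ± 3.15% and 96.1 ± 1.16%, a difference of -66.8 points (adjusted p = 1.69e-32). The other direct differences were -78.9 points for Daam1, -58.4 for Dctn4, -58.2 for Clasp1, -57.6 for Spna2, -38.8 for Col4a1 and -27.8 for Sbf1. Between Srsf11 and Rbfox2 knockdown 6 microexons went opposite ways, with differences of -59.0 points for Daam1, -42.3 for Ptk2, -38.3 for Dctn4, -36.6 for Hook3, -31.2 for Incenp and -26.1 for Col4a1. The 14 direct differences stayed negative without each library of both knockdowns in turn, and were not rerun without a control library. A passing direct contrast was part of the choice of these exons, so this adds no support. The opposite calls against control often rested on single libraries. The fall of Ptk2 with both knockdowns, its rise, and the fall with Srrm3/Srrm4 and rise of Hook3 held without each library. The rise with Rbfox2 knockdown ended for Daam1 without control library c (adjusted p = 0.0698) or b (0.240) or Rbfox2 library d (0.247) or a (0.128), and for Dctn4 likewise (0.241, 0.142, 0.0656 and 0.399). It ended for Sbf1 (0.211, 0.257, 0.114 and 0.340), for Clasp1 without c (0.375), b (0.0639) or d (0.361), and for Spna2 without c (0.160), d (0.0536) or a (0.0555). It ended for Col4a1 without d (0.136), b (0.312) or a (0.110) and for Incenp without c (0.0553) or a (0.113). The fall with Srrm3/Srrm4 knockdown ended for Clasp1 without knockdown library a (0.125) and for Sbf1 without control c (0.351) or knockdown a (0.0627) or c (0.433). The fall with Srsf11 knockdown ended for Dctn4 without control c (0.119) or b (0.0991) or Srsf11 b (0.510), for Hook3 without c (0.305), Srsf11 a (0.0599) or b (0.279), for Incenp without c (0.0749), a (0.0986) or b (0.144), and for Col4a1 without c (0.259) or a (0.0680).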

How the results depend on the processing

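The alternatives were fixed before the data were examined, except leaving out each library in the direct contrasts and a replicate block by library letter, which were added after the results were seen. The planned replicate block was not run because the columns carry no replicate numbers, and a pseudocount did not apply to counts. Control set A and Rnps1 knockdown share the letters a and b, which are not stated to mark a batch. The differences between letters in both groups had a correlation of 0.258 over genes and 0.0039 over events. With the letter as replicate block, 7223 genes, 112 microexons, 1546 longer exons, 685 introns and 221 alternative sites were called for Rnps1. The knockdowns of set B share both letters in the expression table only (correlations -0.0154 to 0.032), and with the block 9079, 8144 and 9216 genes differed directly in the order Srrm3/Srrm4 and Srsf11, Srrm3/Srrm4 and Rbfox2, and Srsf11 and Rbfox2. For the knockdowns of set B against their control no paired analysis was possible because they share fewer than 2 letters. No named gene or named event with a call changed direction under the alternatives run. For named genes without a call, changes of direction were not counted. The balance of rising and falling genes turned for Srrm3/Srrm4, Srsf11 and Rbfox2 with a filter of 5 CPM and with at least a 2-fold change, and for Srsf11 with DESeq2 size factors or the 4 libraries alone. With DESeq2 size factors the medians of 2 lists near 0 changed sign (the unfolded protein response with Rnps1 and decay factors with Srrm3/Srrm4 knockdown). Of the counts and odds ratios 234 alternatives were marked as kept and 67 as moved. A count was kept if it stayed within 1.5 times the reported value. An odds ratio was kept if it stayed on the same side of 1 with the same outcome of the exact test at 0.05. Some odds ratios given below moved by more than 1.5 times and were still marked as kept. Named genes with a call kept it in 3534 alternatives and lost it in 108, and those without a call stayed so in 68 and gained it in 1. Named events kept their call in 512 and lost it in 50. With an estimated correlation 2 list calls held and 36 were lost, and 58 lists without a call gained none. With at least a 2-fold change 1448, 278, 1626 and 900 genes were called for Rnps1, Srrm3/Srrm4, Srsf11 and Rbfox2 knockdown, since small changes drop out. In the same order, limma on log2 odds called 20, 42, 5 and 18 microexons, 396, 16, 33 and 98 longer exons, 118, 0, 4 and 8 introns (with Srrm3/Srrm4 knockdown 2058 introns by limma and 510 by edgeR had an unadjusted p under 0.05) and 77, 4, 2 and 3 alternative sites; the cause was not tested. The rule without a test gave 1181, 167, 433 and 514 introns, 471, 116, 211 and 205 alternative sites, and 281 longer exons for Srrm3/Srrm4. A PSI difference of at least 15 gave 27 alternative sites for Rbfox2 and 9 shared microexons for Srsf11 and Rbfox2, since fewer events can pass. The odds ratios of microexons against longer exons were 1.67, 25.4, 3.01 and 2.76 with a limit of 51 nt, 2.22, 124 and 8.33 (Rnps1, Srrm3/Srrm4, Rbfox2) with limma, and 27.8 and 3.07 (Srrm3/Srrm4, Srsf11) with a control PSI of 20 to 80. Without single libraries 2116 to 3579 genes were called for Srrm3/Srrm4. For Rnps1 the ranges were 75 to 108 microexons, 954 to 1630 longer exons, 344 to 701 introns and 121 to 232 alternative sites, the lowest without Rnps1 library a. For Srrm3/Srrm4 they were 14 to 19 introns and 7 to 14 alternative sites, for Srsf11 38 to 51 microexons, 425 to 494 longer exons, 50 to 72 introns and 33 to 46 alternative sites, the lowest without Srsf11 library a, and for Rbfox2 391 to 481 longer exons, 47 to 87 introns and 22 to 38 alternative sites, the lowest without control library c. The overlaps ranged from 15 to 33 for Rnps1 and Srsf11 (unadjusted exact p = 0.0119 at the lowest) and from 24 to 40 for Srrm3/Srrm4 and Srsf11, and the microexons that differed between Srsf11 and Rbfox2 from 55 to 73. With at least 10 reads in every library few simulated changes of 20 points were recovered.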

Other observations

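The reading-frame tests were written down before their results were seen; the tests of the shared microexon losses and of the exons shared by Rnps1 and Rbfox2 knockdown were chosen after the results were seen. The gene lists and their tests were planned.

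RNA-processing and stress lists not given above moved unevenly between the knockdowns. With Rbfox2 knockdown 16 of 22 hnRNP genes fell and 6 did not pass (camera adjusted p = 0.00787, adjusted p = 0.359 with an estimated correlation), with Hnrnpab at -0.56 ± 0.06. Of 24 neuronal splicing regulators 12 fell, Rbfox2 and Ptbp2 among them, and 5 rose, such as the paralogue Rbfox1 at 0.83 ± 0.10 (adjusted p = 0.00520, adjusted p = 0.302 with an estimated correlation). Of 28 genes of the integrated stress response 15 fell and 3 rose (15 and 4 adjusted over the list alone, adjusted p = 0.00971, adjusted p = 0.460 with an estimated correlation), with Atf3 at -1.45 ± 0.11, and 11 of 18 sympathoadrenal genes rose and 3 fell (adjusted p = 0.0160, adjusted p = 0.302 with an estimated correlation). With Srsf11 knockdown 13 of 19 targets of nonsense-mediated decay fell and 2 rose (adjusted p = 0.0267, adjusted p = 0.188 with an estimated correlation). With Srrm3/Srrm4 knockdown 5 of 12 mitochondrially encoded genes rose and 7 did not pass (6 rose adjusted over the list alone, adjusted p = 0.0287, adjusted p = 0.562 with an estimated correlation).

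The other lists had camera adjusted p above the threshold. With Rnps1 knockdown, genes that rose and fell numbered 3 and 6 of 22 for hnRNP proteins (2 and 5 adjusted over the list alone, adjusted p = 0.961), 4 and 10 of 24 for neuronal splicing regulators (0.0863), 12 and 5 of 28 for the integrated stress response (0.188), 13 and 4 of 30 for S phase (0.207), 4 and 9 of 30 for G2 and M (0.659), 6 and 7 of 17 for sympathoadrenal genes (6 and 9 adjusted over the list alone, 0.312), 5 and 8 of 21 for axon guidance (0.742) and 3 and 1 of 12 for mitochondrially encoded genes (0.595). They were 3 and 2 of 40 for ribosomal proteins (1 and 2 adjusted over the list alone, 0.659), 3 and 5 of 10 for fibroblast markers (3 and 6 adjusted over the list alone, 0.961), 1 and 5 of 15 for long neuronal genes (0.231) and 17 and 23 of 90 for microexon genes (0.312), and 4 of 7 glial markers fell (0.207). For p53 targets, 5 and 5 of 24 (4 and 5 adjusted over the list alone, 0.961), the median (0.02) and mean (-0.04) differed in sign. For the unfolded protein response, 8 and 3 of 20 (0.528), the median was near 0 and changed sign with DESeq2 size factors.

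With Srrm3/Srrm4 knockdown, again with the camera adjusted p in parentheses, genes that rose and fell numbered 1 and 5 of 22 for hnRNP proteins (0.302), 2 and 4 of 19 for decay targets (0.474), 5 and 5 of 28 for the integrated stress response (6 and 5 adjusted over the list alone, 0.934), 2 and 8 of 23 for p53 targets (0.225), 3 and 2 of 27 for interferon response (0.433), 1 and 3 of 9 for histones (1 and 4 adjusted over the list alone, 0.202) and 8 and 5 of 18 for sympathoadrenal genes (9 and 6 adjusted over the list alone, 0.0728). They were 1 and 2 of 6 for glial markers (1 and 3 adjusted over the list alone, 0.560), 3 and 1 of 16 for long neuronal genes (0.129), 7 and 21 of 92 for microexon genes (10 and 24 adjusted over the list alone, 0.0728) and 1 and 1 of 40 for ribosomal proteins, neither of which passed adjusted over the list alone (0.934). Of 19 SR genes 2 fell (1 adjusted over the list alone, 0.372), of 18 genes of the exon junction complex 2 fell (1 adjusted over the list alone, 0.555) and of 30 G2 and M genes 5 fell (0.589). For axon guidance, 3 and 6 of 22 (0.959), the test pointed down and the median up (0.04), and for decay factors, 2 and 1 of 15 (0.786), the median near 0 changed sign with DESeq2 size factors.

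With Srsf11 knockdown they numbered 5 and 11 of 24 for neuronal splicing regulators (0.0594), 4 and 10 of 15 for decay factors (0.188), 9 and 6 of 23 for p53 targets (9 and 7 adjusted over the list alone, 0.352), 5 and 16 of 30 for G2 and M (0.105), 11 and 25 of 44 for neuronal differentiation (0.0594), 4 and 9 of 20 for the unfolded protein response (0.188), 6 and 1 of 12 for mitochondrially encoded genes (0.352), 10 and 5 of 16 for long neuronal genes (0.283) and 24 and 40 of 92 for microexon genes (26 and 40 adjusted over the list alone, 0.0980), and 3 of 6 glial markers rose (0.126). Median and mean differed in sign for sympathoadrenal genes (7 and 8 of 18, -0.13 and 0.11, 0.600) and axon guidance (6 and 11 of 22, -0.12 and 0.08, 0.129). With Rbfox2 knockdown they numbered 3 and 7 of 19 for SR proteins (3 and 8 adjusted over the list alone, 0.532), 2 and 9 of 18 for the exon junction complex (0.200), 4 and 4 of 15 for decay factors (0.811), 3 and 7 of 19 for decay targets (3 and 8 adjusted over the list alone, 0.369), 3 and 6 of 23 for p53 targets (2 and 6 adjusted over the list alone, 0.486), 12 and 20 of 44 for neuronal differentiation (0.0726), 4 and 7 of 20 for the unfolded protein response (0.419), 5 and 2 of 12 for mitochondrially encoded genes (0.419), 7 and 5 of 40 for ribosomal proteins (0.692), 2 and 1 of 6 for glial markers (0.369) and 37 and 30 of 92 for microexon genes (37 and 33 adjusted over the list alone, 0.369), and 5 of 9 histone genes rose (6 adjusted over the list alone, 0.186). Too few immune markers were measured for a test. Among them Cd74 rose from 8.49 ± 0.898 to 26.7 ± 3.23 CPM with Srsf11 knockdown (1.65 ± 0.12), and stood at 6.55 ± 0.245 CPM with Rbfox2 knockdown (adjusted p = 0.0284), a call that ended without control library c (0.163) and without Rbfox2 library a (0.132) or b (0.0584).

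Microexons that fell with Srrm3/Srrm4 knockdown also fell with Rnps1 knockdown, 72 of 124, against 36 of 362 of the others, and with Srsf11 knockdown, 42 of 126, against 21 of 461. Less Srrm3 and Srrm4 mRNA as in their own knockdown was not seen: the lower of both log2 changes was -0.1011 with Rnps1 knockdown (lower 95% bound -0.5335) and 0.06007 with Srsf11 knockdown (-0.1036). A general loss of short exons of mid-range inclusion (control PSI 20 to 80) would strike both kinds alike at equal read numbers. Among the others 26.98% fell with Rnps1 knockdown against 56.14% (Fisher exact p = 0.001544). Exons with more reads are called more easily with either knockdown, and both kinds were not matched for reads. The gap, and those with Srsf11 knockdown below, therefore do not decide about a general loss. Srsf11 and Srrm3/Srrm4 share controls, so each was set against another control library, both ways: among the others 14.71% fell with Srsf11 knockdown against 36.54% (Fisher exact p = 0.009148), and 12.5% against 32.69% the other way (Fisher exact p = 0.007815). In these fits the single control library was assumed to vary like the other groups. They replaced a first test with both control libraries in common (17.91% against 47.37%), which is left aside because noise of the controls enters both knockdowns there. For Srsf11 the shared controls gave a covariance of at most 8.92 in simulations against the observed 92.37. At the simulated spread they were not the whole source of the covariance. That spread was a single value pooled over the groups of set B, and noisier controls were not simulated. No microexon was called to fall in the simulations, so they do not decide about the overlap of calls, to which the controls may add. Rnps1 mRNA stood at 76.4% of control with Srsf11 knockdown, and whether this adds to the losses there was not tested. A candidate explanation that stays open is that Rnps1 and Srsf11 act at many of the microexons that Srrm3 and Srrm4 act on. Protein levels and binding were not measured.

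Exons that fell with Rbfox2 knockdown tended to fall with Rnps1 knockdown, which has other controls. Of longer exons 186 fell with both, where 34.7 would be shared by chance if all tested exons were alike. The median change of 562 fallen exons was -9.543 points (bootstrap 95% interval -11.05 to -8.135). For the 178 of them with a control PSI of 20 to 80 it was -15.24 points (-18.15 to -11.86). Rbfox2 mRNA was lower with Rnps1 knockdown, and if that were the source, exons that rose with Rbfox2 knockdown should rise; their median was 2.451 points (-2.075 to 7.439, n = 76), which leaves this open. The same 76 exons were first used to test a general skipping of exons and decided nothing, so a second test, chosen after that, took exons of control PSI 20 to 80: the 44 that rose had a median of 8.572 points (-4.599 to 11.03) and 1727 uncalled ones -6.438 points (-7.218 to -5.204). These intervals only just stay apart, which argues weakly against a general skipping as the whole source. The lower Rbfox2 mRNA and a shared action on these exons may both contribute and were not told apart. Rnps1 mRNA was in turn lower with Rbfox2 knockdown, at 80.3% of control, which was not tested as a source.

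Skipping of an exon whose length is not a multiple of 3 shifts the reading frame and may expose the message to nonsense-mediated decay. With Rnps1 knockdown, 552 genes with such a fallen exon had a median log2 change of -0.1702 and 465 genes with a frame-keeping one -0.02147, a difference of -0.1488 (permutation test, 2-sided, p = 2e-05, adjusted p = 8e-05 over 4 tests). The difference was -0.03618 with Srrm3/Srrm4 knockdown (permutation p = 0.3802, adjusted p = 0.7169), where 20 genes had a frame-shifting exon, -0.009885 with Srsf11 knockdown (permutation p = 0.7702) and -0.01374 with Rbfox2 knockdown (permutation p = 0.5377, adjusted p = 0.7169). These 3 tests decide nothing, and whether the knockdowns differ was not tested. The difference with Rnps1 knockdown is consistent with a loss of frame-shifted messages in part, and a lower transcription of the same genes was not excluded.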
